A study of Picea abies with 21 samples.

How the data were processed

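The samples were 21 spotted cDNA arrays, each hybridised with cDNA from the cambium, the dividing layer beneath the bark, of 2 Norway spruce (Picea abies) ramets. A ramet is a separate plant propagated from a clone, and 11 ramets of 3 clones were used. Ramets that shared a clone were never compared on 1 array while both infected, so clone means were reached through a loop of arrays in which every ramet was linked to others. Per the labels' protocols, total RNA was turned into cDNA with a PCR-based kit and labelled with Cy5 or Cy3 by the Klenow method. PCR amplification before labelling can alter the abundance of single transcripts, and no value here measures that.

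Per the file headers, the authors quantified each scanned slide in QuantArray, and the deposited spot values are intensity readings for Cy5 and Cy3 with a local background, without background subtraction or crosstalk correction. Each slide held 5376 spots in 48 subarrays of 112. The authors also deposited a table with 1 value per spot and array, used here as a score because its scale, centring and direction are not stated. Against the spot intensities its values ran as Cy3 over Cy5, with correlations with log2 of Cy5 over Cy3 between -0.957 and -0.527 over the 21 arrays. Its slope on a difference of intensities logged on base 2 in succession, with the trend in brightness removed, lay between -1.15 and -0.688, so the direction was settled from the values while the scale and centring stay unknown. Its column medians were -0.00055, 0.00135, -0.00035, -0.0056, 0.0113, -0.0125, -0.0178, -0.0094, -0.0053, 0.0012, -0.0016, 0.0004, -0.0522, -0.01955, -0.0132, -0.0005, -0.002, -0.0059, -0.0071, -0.0108 and 0.0004.

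From the intensities, background was corrected by normexp with an offset of 50, and log2 of Cy5 over Cy3 was normalized within each array by a global loess curve with a span of 0.3. Spots that the quantification had marked to be ignored were left out. They made up 0.0372% to 13.8% of an array. Control spots could not be told from others, because no spot carried a name in the files used here, and none was left out. Neighbouring pairs of subarray columns held the same pattern of brightness, with correlations of 0.979 to 0.994 against at most 0.505 for any other pair of subarrays. The 2 spots at matching places were therefore averaged as 1 probe, which gave 2688 probes. This pairing rests on the intensities alone. Probes are named below by the numbers of their 2 spots.

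A filter on dim probes asked for a foreground above local background by 2 background SDs in at least 50% of the channels of a group. It removed 0 probes, since 100% of spots passed in every channel. The median local background of an array was at most 77.7 in Cy5 and 500.5 in Cy3, and 0 on most arrays in Cy5. The filter therefore tested nothing about brightness. Median intensity per array ran from 723 to 8611 in Cy5 and from 746 to 4059 in Cy3, and at most 60 spots of a channel were saturated. The number of arrays limits the precision of every value.

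The fit had 2 steps, fixed before the data were examined. Least squares over all arrays gave each probe a level for each of the 11 ramets, relative to their mean, together with a dye term. limma (lmFit and eBayes) then compared the ramet levels with 1 mean per group over 5 groups, 6 residual degrees of freedom and a prior worth 4.85. Probes with a Benjamini-Hochberg adjusted p under 0.05 passed. Ramets counted as replicates and arrays did not. Each wounded group had 1 ramet, whose spread was assumed to be that of the other groups. The work used R 4.3.3, limma 3.58.1, statmod 1.5.0 and, for the plots, matplotlib 3.10.9.

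The steps were tested on simulated data for 2688 probes, with the array variances of these arrays and the ratio of ramet to array variance estimated from them (0.181). For medium over low clone, 70.1% of probes changed by 1 on the log2 scale passed, 13.4% of those changed by 0.5 and 98.5% of those changed by 2. For infected over wounded in the medium clone these shares were 25.4%, 1.49% and 90.9%. At a ratio of 1, a change of 1 passed for 19.4% and 0% of probes in these 2 comparisons, so the power depends on that ratio. The simulation held no trends over the slide. It changed 67, 67 and 66 probes by 0.5, 1 and 2 at once. The share that passes after Benjamini-Hochberg adjustment depends on how many probes change, so it would be lower with fewer changed probes. In the real arrays 14 probes had an estimated medium-over-low difference beyond 2-fold.

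Since no probe was paired with a gene, the 20 gene lists fixed beforehand (defence, cell wall, stress, housekeeping and fungal genes among them) could not be searched, and 0 were tested by camera or fry. The rule for naming probes was therefore the one written for that case: at most 2 higher and 2 lower probes per comparison, by the smallest adjusted p and, where tied, the smallest p.

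Alternatives were no background correction, median centring, loess within each subarray, other filters, ignored spots kept, no dye term, dye-swapped arrays averaged first, a 1-step model with a consensus ratio of ramet to array variance, arrays taken as independent, a replicate block, slides of 1 number series, the authors' score table and each ramet left out. Those added after the data were seen were single spots as features, a dye term per quantification session, the dimmest 25% of probes left out, the consensus model together with subarray loess, and 18 arrays without the 3 whose headers leave the dyes blank. The labels conflict on the fungus and time: the treatment protocol names Heterobasidion parviporum and 20 days, the title names Heterobasidion annosum, and the design text gives 1 month.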

Results

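Cambial gene expression was measured in 3 clones of Norway spruce graded by their resistance to Heterobasidion, the basidiomycete that causes root and butt rot of conifers. Of each clone (low, medium and high resistance), 3 ramets had been cut and inoculated with the fungus. The low and medium clones each had 1 further ramet that was wounded and given sterile agar, while the high clone had no wounded ramet. The 11 ramets were compared on 21 arrays with Cy5 and Cy3 labels, between 3 and 5 arrays per ramet, and 3 pairs of ramets were hybridised again with the dyes swapped. Levels are given as log2 values relative to the mean of the 11 ramets, with SD over 3 ramets where a group has 3. No probe could be tied to a gene, so probes are named by their spot numbers and nothing is said of their function.

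Arrays differed in quality. The log ratios of the duplicate spots of a probe correlated between 0.256 and 0.753 within an array after global loess, with a median of 0.538. Loess within each subarray lowered this to a range of 0.149 to 0.714, with a median of 0.412. After global loess, a median of 28.1% of the variance of the log ratios lay between subarrays, with a range of 4.20% to 49.2%. The level of a ramet varied over probes with an SD of 0.227 to 0.413. The first principal component of the levels held 36.5% of their variance, with the low-clone wounded ramet at 16.6 and the medium-clone wounded ramet at -15.7. Infected ramets of the high clone were spread along it, at -3.50, -8.25 and 10.3.

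**Figure D1:**
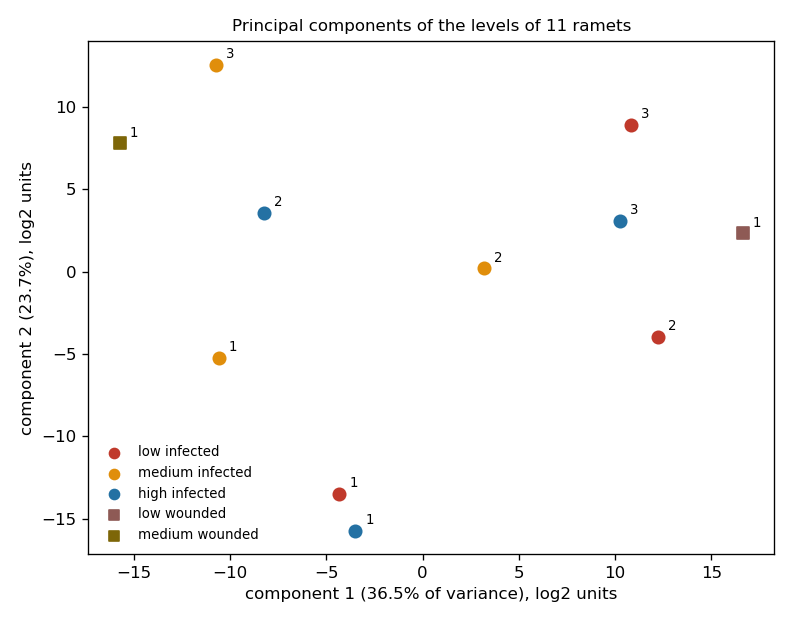
Principal components 1 (36.5% of variance) and 2 (23.7%) of the levels of 11 ramets, in log2 units. Circles are infected and squares wounded ramets, coloured by clone and marked with the ramet number. The wounded ramets lie at 16.6 and -15.7 on component 1, and the 3 infected ramets of each clone are spread apart.

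The first comparison asked how infected tissue differs between the clones. Each grade of resistance was a single clone, so no difference between clones can be assigned to resistance. Between the medium and the low clone, probe 3908/4020 stood at 0.66 ± 0.14 in the low clone and -0.49 ± 0.13 in the medium clone (SD, n = 3 each), a log2 difference of -1.16 (SE 0.20) or 2.23-fold. Probe 4305/4417 was lower in the medium clone by a similar amount, at -0.35 ± 0.20 against 0.60 ± 0.18, a difference of -0.94 (SE 0.19). Probe 518/630 was higher there, at 0.80 ± 0.28 against -0.53 ± 0.43, a difference of 1.33 (SE 0.30) or 2.51-fold, and probe 70/182 by 1.11 (SE 0.25). None of the 4 passed in limma after adjustment, with adjusted p from 0.303 to 0.324.

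Over all 2688 probes, 0 passed by limma between the medium and the low clone, while 196 had an unadjusted p under 0.05 (92 higher, 104 lower in the medium clone) where 5% of all probes are 134.4. Leaving out 1 infected ramet (given as clone and ramet number) moved this count to 86 without low 2 and to 104 without medium 3. Slides of 1 number series moved it to 336. Loess within each subarray changed this result: 29 probes passed, 16 higher and 13 lower in the medium clone, with absolute log2 differences of 0.61 to 1.45 and 365 probes under 0.05. All 29 had the same sign after global loess and 26 of them an unadjusted p under 0.05 in limma there. The 29 were picked by their p in the same arrays, so this is no independent test of them. Among the named probes, 3908/4020 (-0.96, SE 0.15, adjusted p 0.0162), 4305/4417 (-0.67, SE 0.13, adjusted p 0.0264) and 518/630 (0.92, SE 0.17, adjusted p 0.0264) passed with subarray loess, and 70/182 did not (0.84, SE 0.19, adjusted p 0.0549). A 1-step limma model with a consensus variance ratio passed 20 probes after global loess, 9 of them shared with those 29. The interval of a difference had a median 95% half-width of 0.49 after global loess, and for 82.2% of probes it lay wholly within a 2-fold change. With subarray loess these values were 0.31 and 97.2%.

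**Figure D2:**
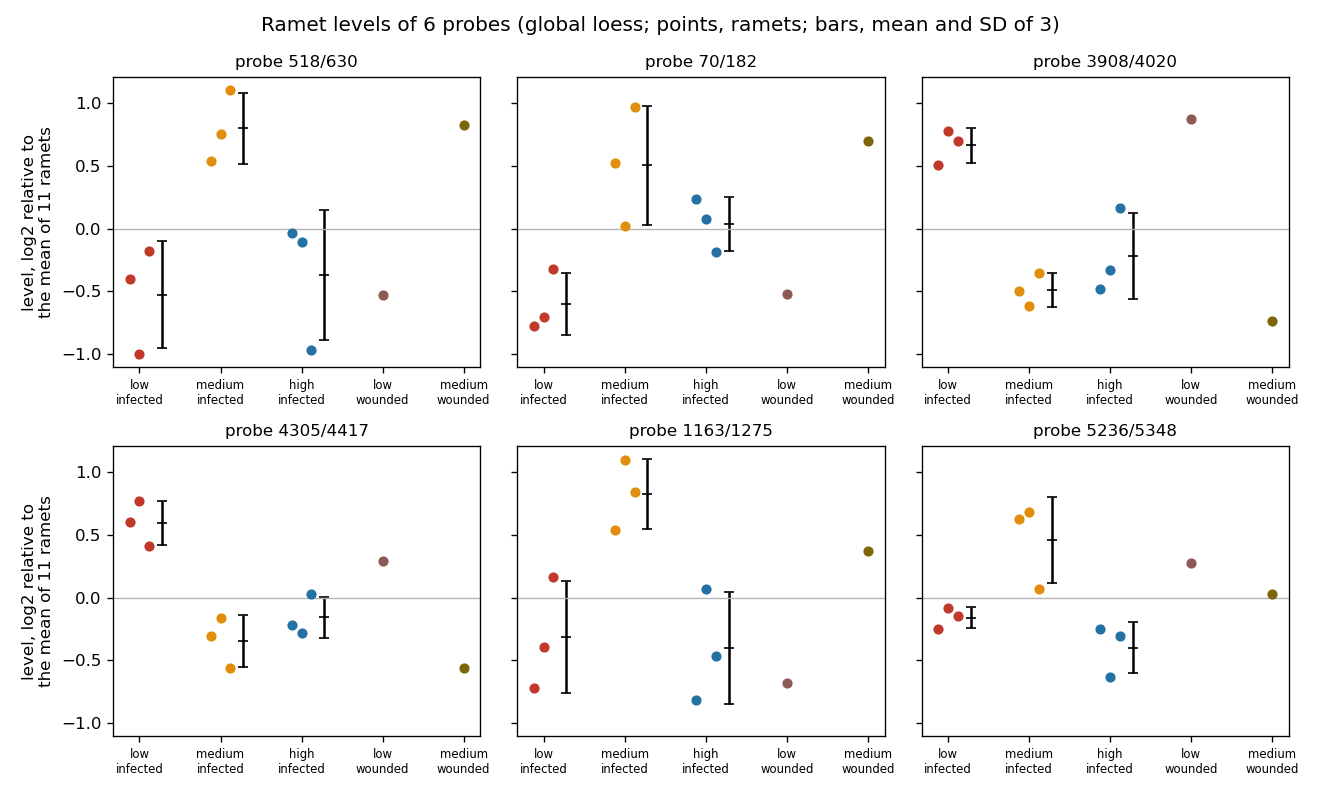
Levels of 6 probes in the 11 ramets after global loess, as log2 relative to the mean of all ramets. Points are ramets, and bars the mean and SD of 3 infected ramets of a clone. Probe 3908/4020 lies at 0.66 in the infected low clone and -0.49 in the infected medium clone, and at 0.88 and -0.74 in the wounded ramets of these clones, which share arrays with infected ramets.

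Between the high and the low clone, probes 3908/4020 and 4305/4417 had the smallest p among lower probes, in a comparison that shares the 3 low-clone ramets with the one above. Their log2 differences were -0.88 (SE 0.20) and -0.75 (SE 0.19), with levels of -0.22 ± 0.34 and -0.16 ± 0.16 in the high clone (SD, n = 3). Probe 84/196 stood higher in the high clone by 1.03 (SE 0.29) and probe 308/420 by 0.73 (SE 0.20). limma passed 0 probes here, the 4 named ones having an adjusted p of 0.966, and 119 probes lay under an unadjusted 0.05 (40 without low 1, 34 without low 2, 39 without medium 2, 211 without high 3). This count was 193 with median centring, 201 with the replicate block and 70 with slides of 1 number series. With subarray loess 0 passed and 261 lay under 0.05, and the consensus model after global loess passed 0 with 253 under 0.05.

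Between the high and the medium clone, probe 1163/1275 had the lowest p, with -0.40 ± 0.45 in the high and 0.83 ± 0.28 in the medium clone (SD, n = 3 each), a difference of -1.23 (SE 0.28) or 2.35-fold. Probe 5236/5348 followed with a difference of -0.86 (SE 0.21). Probes 2474/2586 and 2017/2129 were higher in the high clone, by 0.71 (SE 0.17) and 0.85 (SE 0.23). limma passed 0 probes after global loess, all 4 having an adjusted p of 0.719, and 114 lay under an unadjusted 0.05 (186 without low 1, 47 without medium 2, 66 without medium 3). With subarray loess 6 probes passed, all lower in the high clone, with absolute log2 differences of 0.85 to 1.39. Among them were 1163/1275 (-1.39, SE 0.25, adjusted p 0.0355) and 5236/5348 (-0.86, SE 0.15, adjusted p 0.0355). Of the 6, probes 1163/1275, 2118/2230, 2699/2811 and 518/630 had also passed for medium over low with subarray loess, higher in the medium clone. Both comparisons share the medium-clone ramets, so these calls are not independent of those for medium over low. The consensus model after global loess passed 0 with 209 under 0.05.

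An F-test in limma over the 3 infected clones together passed 0 probes after global loess, with 149 under an unadjusted p of 0.05 (81 without low 2, 96, 75 and 98 without medium 1, 2 and 3). The same test passed 16 probes with subarray loess and 19 with the consensus model. With the consensus model and subarray loess together, a choice made after the data were seen, 124 probes passed for medium over low, 45 for high over low and 39 for high over medium. Arrays taken as independent replicates, which ignores that they share ramets, gave 163, 75 and 52.

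Of the 10 probes named in the 3 pairwise clone comparisons, 5 lay in column 14, the last of their subarray (518/630, 70/182, 308/420, 84/196 and 5236/5348), which holds 7.14% of all probes. Neither loess corrects for columns inside a subarray. Over all probes, counted after these places were seen, column 14 held 18 of the 196 under 0.05 for medium over low after global loess, and 3 of the 29 that passed there with subarray loess. For high over medium it held 15 of 114 under 0.05 after global loess, and 33 of 291 and 2 of the 6 passing with subarray loess. For high over low it held 11 of 119 and, with subarray loess, 27 of 261. In high over medium it held more probes under 0.05 than any other column. A place effect on these 5 probes is not excluded.

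**Figure D3:**
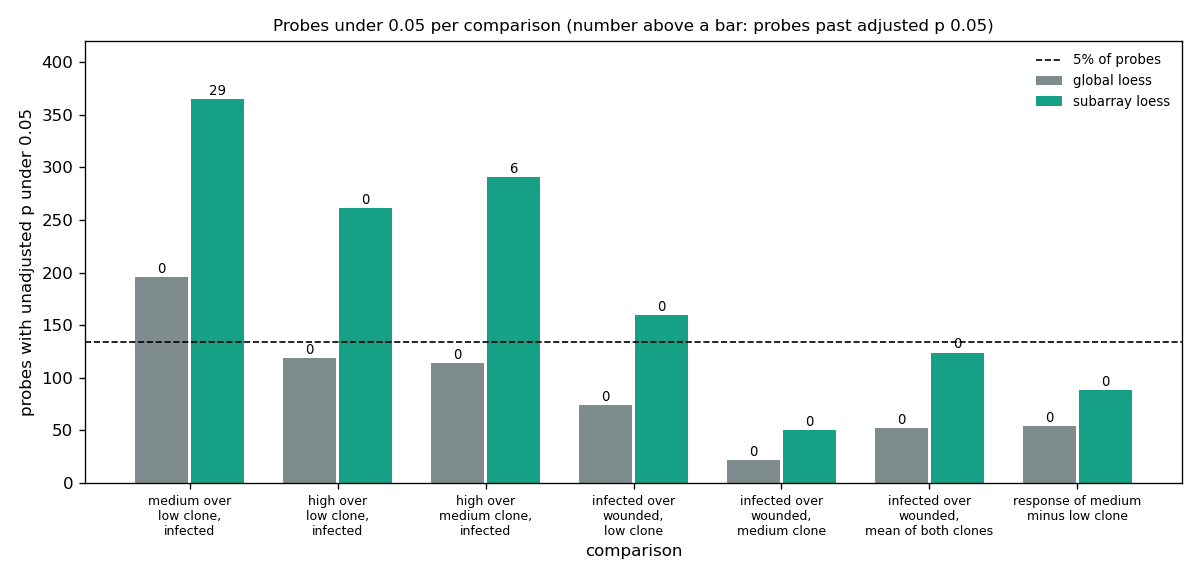
Number of the 2688 probes with an unadjusted p under 0.05 in each of 7 comparisons, after global loess (grey) and after loess within each subarray (green). The dashed line marks 5% of probes, 134.4. In simulated data unchanged probes lay under 0.05 in 4.10% of cases for medium over low and in 1.53% for infected over wounded in the medium clone. The number above a bar counts probes past an adjusted p of 0.05: 29 and 6 in 2 clone comparisons with subarray loess, and 0 in the others.

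Arrays had been quantified in 5 sessions, which held 1 to 9 arrays. With a dye term for each session, limma passed 0 probes in each of 7 contrasts and in the F-test, with 198, 123 and 84 probes under an unadjusted 0.05 for medium over low, high over low and high over medium. Within a session, arrays being taken as replicates, the clone differences could be estimated in 3 sessions, with 0 probes passing and 7 to 296 under 0.05. These fits had 1, 4 and 1 residual degrees of freedom, so that 0 says little. Over probes, medium-over-low differences within a session correlated with those from the other sessions at 0.482, 0.387 and 0.459. High-over-low values gave 0.308, 0.457 and 0.306, and high-over-medium values 0.169, 0.378 and 0.224. Sessions shared ramets, and probes are not independent replicates.

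The response to the fungus beyond wounding was compared in the low clone, 3 infected ramets against 1 wounded ramet. Probe 4332/4444 stood at 0.49 ± 0.17 in the infected ramets (SD, n = 3) and at -0.86 in the wounded ramet, a difference of 1.35 (SE 0.31) or 2.54-fold. Probe 4342/4454 differed by 1.24 (SE 0.26), from -0.96 in the wounded ramet to 0.28 ± 0.25 in the infected ramets. Probes 2301/2413 and 1571/1683 had lower levels in infected ramets, with differences of -0.92 (SE 0.30) and -0.71 (SE 0.23). limma passed 0 probes, with an adjusted p of 0.982 for all 4, and 74 lay under an unadjusted 0.05 (15, 158 and 140 without low 1, 2 and 3, 18 without medium 2, 250 without high 3). Subarray loess passed 0 with 160 under 0.05, where 4342/4454 had 1.12 (SE 0.18, adjusted p 0.0667), and the consensus model with subarray loess, added after the data were seen, passed 3 probes: 4332/4444, 4342/4454 and, singled out after its value was seen, 4368/4480. Arrays taken as independent passed 1, 4342/4454.

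In the medium clone, probes 3860/3972 and 2981/3093 were higher in infected ramets than in the wounded ramet by 0.87 (SE 0.28) and 0.85 (SE 0.29). Probes 1378/1490 and 985/1097 had differences of -0.84 (SE 0.29) and -1.20 (SE 0.44). Probe 3860/3972 stood at 0.02 in infected ramets and -0.84 in the wounded ramet. Probe 2981/3093 stood at -0.30 and -1.15, with 0.34 in infected low-clone and 0.25 in infected high-clone ramets. Its infected level was thus not raised against the other clones. The dye-swapped arrays of infected ramet 3 and the wounded ramet of this clone correlated at 0.350, where a swap turns the sign. limma passed 0 probes, at an adjusted p of 0.999 for the 4, with 22 under an unadjusted 0.05 (8 and 13 without low 1 and 2, 65, 0 and 63 without medium 1, 2 and 3, 43 and 36 without high 2 and 3). Subarray loess passed 0, with 50 under 0.05. The consensus model with subarray loess passed 1 probe, 2574/2686, at -1.02 (SE 0.18, adjusted p 0.0204), which was singled out after its value was seen. The median 95% half-width of an infected-over-wounded difference was 0.69 after global loess, wider than the 0.49 between infected clones, and 0.44 with subarray loess. These widths ignore errors correlated through shared arrays. Array error alone correlates the wounded ramet with infected ramets 1, 2 and 3 at 0.502, -0.182 and 0.497 in the medium clone. In the low clone these values are -0.153, 0.413 and -0.125. Counts under 0.05 for the 2 clones are therefore not on one scale.

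Averaged over both clones, infected minus wounded was 0.68 (SE 0.22) for probe 5028/5140 and 0.63 (SE 0.22) for probe 4332/4444. Probes 2712/2824 and 1571/1683 had differences of -0.65 (SE 0.22) and -0.48 (SE 0.16). Probe 4332/4444 stood at 0.49 infected and -0.86 wounded in the low clone, but at -0.31 and -0.23 in the medium clone. Its mean is therefore not a rise in both clones. Probe 5028/5140 stood at 0.14 and -0.94 in the low clone and at 0.22 and -0.06 in the medium clone. limma passed 0, at an adjusted p of 0.999, with 52 probes under an unadjusted 0.05 (10 and 88 without low 1 and 3, 3 and 82 without medium 2 and 3, 82 and 165 without high 1 and 3), and subarray loess passed 0 with 124 under 0.05. The consensus model after global loess passed 0 for the low clone, the medium clone, their mean and the difference between them, with 114, 104, 121 and 89 probes under 0.05. For 88.1% of probes the 95% interval of this mean response lay within a 2-fold change after global loess, and for 99.4% with subarray loess.

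Within-session values for infected over wounded could be had in 1 session for the low clone and in 2 for the medium clone, with 0 probes passing, at 1 or 4 residual degrees of freedom, and 86 to 216 under 0.05. These differences correlated over probes with the other sessions at 0.0993 for the low clone, and at 0.176 and 0.231 for the medium clone.

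The difference between the responses of the medium and low clones was tested directly. Probes 4342/4454 and 4332/4444, named above for the low clone, had values of -1.43 (SE 0.37) and -1.43 (SE 0.43) for the medium minus the low response. In 4342/4454 the low-clone wounded ramet stood at -0.96, and all other ramets lay between -0.25 and 0.56. In 4332/4444 it stood at -0.86, and all others lay between -0.55 and 0.68. That wounded ramet enters both the low-clone response and this difference, so these are not separate results. Probes 3020/3132 and 2540/2652 had a response higher in the medium clone by 1.49 (SE 0.48) and 1.24 (SE 0.41). limma passed 0 probes, at an adjusted p of 0.970 for these 4, with 54 under an unadjusted 0.05 (12 and 83 without low 1 and 2, 10 without medium 2, 124 without high 3). Subarray loess passed 0 with 88 under 0.05 and a lowest adjusted p of 0.0511. The consensus model with subarray loess passed 5 probes, all with a lower response in the medium clone: 4342/4454 (-1.27, SE 0.21, adjusted p 0.0042), 4332/4444 (-1.42, SE 0.25, adjusted p 0.0063) and, singled out after their values were seen, 2574/2686, 2538/2650 and 4368/4480. Arrays taken as independent passed 3: 4342/4454 and 2540/2652, and 2574/2686, singled out likewise. The median 95% half-width was 0.98 after global loess and 0.63 with subarray loess. By their spot numbers, 4342/4454, 4332/4444 and 4368/4480 lie in the same pair of neighbouring subarrays (row 10, columns 3 and 4). Probes 2540/2652, 2574/2686 and 2538/2650 share another pair (row 6, columns 3 and 4). Every probe passed for a response or the difference in response, under any setting, is among these. A place effect on them is not excluded.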

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

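The tests chosen only after the result was seen were, in this part, that of the dye swap with subarray loess, and the counts among splits with 0 or 1 array inside their parts, among splits with up to 3 and with 4 to 6 such arrays, and among splits with a part of 1 ramet number.

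Among 24 sets of arrays compared on quality measures, 3 held an array far from the rest, where chance gives about 1 in 20 (1.2 sets). The array of low-clone infected ramet 2 with high-clone infected ramet 1 had log ratios with an SD of 0.890, against 0.391 to 0.473 on the other 3 arrays of low and high infected ramets. The same array had 6.32% of spots ignored, against 0.874% to 1.69%. The array of medium-clone infected ramet 3 with low-clone infected ramet 3 had an SD of 0.763, against 0.330 to 0.420 on the other 4 of its kind. That array was quantified years after the rest and with another gridding protocol, and its header leaves the dyes blank. The remaining arrays with blank dyes had similar SDs, though the rule within kinds did not flag them. Medium-clone infected ramet 1 (Cy5) with the medium-clone wounded ramet gave 0.813. High-clone infected ramet 1 (Cy5) with the low-clone wounded ramet gave 0.737. The median over all arrays was 0.445. Both of these arrays carry a wounded ramet. The array of high-clone infected ramet 3 (Cy5) with the low-clone wounded ramet (Cy3) has a slide number that differs by 1 digit between its header and its label. Its ramets were taken from the label, and it correlated at -0.247 with its dye swap.

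Arrays with swapped dyes should correlate negatively. The swap of high-clone infected ramet 3 with the low-clone wounded ramet gave -0.247 and that of medium-clone infected ramet 1 with the medium-clone wounded ramet -0.194, but the swap of medium-clone infected ramet 3 with the medium-clone wounded ramet gave 0.350. A wrong dye label on 1 of these arrays was argued against, since both correlated above 0 (0.0661 and 0.117) with what the other 19 arrays gave for the same ramets. With the other array of the swap left in, the 2 gave -0.154 and -0.185, values that rest in part on the array in doubt. A dye bias of single probes did not account for it either, the correlation staying at 0.278 once each probe's dye term was subtracted. With subarray loess it fell to 0.0105, so a trend over the slide may have produced the positive value. The first and second swaps then gave -0.485 and -0.135, and no biological explanation was tested.

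More probes passed with subarray loess than with global loess, 29 against 0 for medium over low. A more flexible curve alone was argued against: with spots shuffled over the 48 subarrays, 0 of 20 shuffles passed as many probes, and none passed any. The median share of variance between subarrays was 0.281, and the median residual SD between arrays dropped from 0.357 to 0.239. Trends over the slide that hide clone differences are a candidate explanation. The clone differences themselves remain a hypothesis.

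For medium over low with subarray loess, 1 of 10 splits of the 6 ramets, the real one, gave 29 probes, and the highest of the others gave 0. For high over medium the real split gave 6 and the highest other 0, again 1 of 10. After global loess each of the 3 pairwise clone comparisons gave 0 probes in all 10 splits. With 10 splits a share under 0.05 cannot be reached. For the F-test over 9 infected ramets, 100 of 280 splits were drawn. A second draw with other random numbers was also seen, and the first was kept. The second read the same way for all 3 tests, with lower highest counts. With subarray loess 2 of the 100 kept, the real one included, gave at least its 16 probes (highest other 26), and with the consensus model 2 gave at least its 19 (highest other 22), a share under 0.05 of the drawn splits for both. The drawn splits are not all alike, since the real one has 0 arrays that compare ramets inside a part and others have up to 6. Among the 17 drawn splits with 0 or 1 such array, 1 gave at least 16 with subarray loess (highest other 8) and 2 at least 19 with the consensus model (highest other 22), and 17 splits are too few for a share under 0.05. After global loess the real split gave 0, which all 100 reach by definition, so nothing about chance follows.

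The highest other split after global loess gave 123 probes. It kept 6 arrays inside its parts. All 62 drawn splits with up to 3 such arrays gave 0 probes, and the 4 splits that gave any were among the 38 with 4 to 6, of which 34 gave 0. Array error shared inside parts therefore stays open. One of its parts was the 3 infected ramets numbered 1, whose pairs correlated at 0.413 to 0.538 in their deviations from clone means. Of the 4 drawn splits with that part 3 gave 0 probes, so the reason for the 123 probes was not identified.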

How the results depend on the processing

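After global loess every count of passing probes was 0, and it stayed at 0 in all 8 comparisons without background correction, with median centring, without a filter, with the filter on all channels, with ignored spots kept, without a dye term, with dye swaps averaged first, with slides of 1 number series, and, added later, with a dye term per session, without the dimmest 25% of probes, with single spots and without the 3 arrays whose headers name no dye. Leaving out each ramet gave 0 to 0 probes in each comparison that could still be made. The filters removed nothing and tested nothing. Subarray loess raised medium over low to 29, high over medium to 6 and the F-test to 16, where a median share of 0.281 of the variance lay between subarrays. The consensus model gave 20 for medium over low and 19 for the F-test. In simulated data at the ratio of 0.181, it passed 85.1% of probes changed by 1 for medium over low. The 2-step fit passed 70.1% of them. Unchanged probes lay under 0.05 in 5.06% of cases with the consensus model and in 4.10% with the 2-step fit. Whether this greater power accounts for the 20 and 19 was not tested. Arrays taken as independent gave 163, 75 and 52 for medium over low, high over low and high over medium, 197 for the F-test, 1 for infected over wounded in the low clone and 3 for the difference in response. That setting treats repeats of a ramet as replicates, and in simulated data 12.8% of unchanged probes had p under 0.05 there. The score table gave 1 for medium over low, probe 518/630 (the cause was not tested). The consensus model with subarray loess gave 124, 45 and 39 for the clone pairs, 154 for the F-test, 3 and 1 for infected over wounded in the low and medium clone, and 5 for the difference in response, with 0 for the mean response.

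With the ramet number as a replicate block, 0 probes passed in each comparison, with 261, 201 and 175 under 0.05 for the clone pairs. Counts under 0.05 also rose above those of the main fit for both responses, their mean and their difference. The numbers were not taken as pairing: 6 of 9 same-numbered pairs deviated together above 0.1, over a range of -0.417 to 0.538 (0.413 to 0.538 for the 3 pairs numbered 1), and 6 of 9 infected ramets correlated best with their own number. Pairs of the low and medium clones gave 0.538, 0.478 and 0.474 for numbers 1, 2 and 3, and every negative value involved the high clone. No block was fitted with subarray loess, so a pairing in medium over low there was not tested. Of 812 recomputed fold changes of named probes, 774 kept their side of the threshold, 38 moved past it and 0 changed sign. These probes were picked by their p in the same arrays, and the filter settings repeat the main fit. Stable signs here are therefore no independent test. Gene lists could not be tested, so no estimated correlation or fry result exists. The median local background ran from 0 to 500.5 in Cy3 and from 0 to 77.7 in Cy5 over arrays, and no limit from signal over background was set.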

Other observations

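The tests of the wounded ramets at the 29 probes and of the clone with subarray loess were chosen after the data were seen. For the wounded ramets the rule for reading the test was also changed after its result, which the first rule had read as not fitting a shared clone difference.

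The ramets resembled each other in ways that follow the loop. Over the 55 pairs of ramets, the correlation of levels rose with the one that shared array error alone gives (r = 0.768, pairs not being independent), so the wounded ramets at opposite ends of the first component may owe their place to the arrays they shared. Beyond that error, pairs of the same clone exceeded other pairs by 0.0677 after global loess (exact permutation p = 0.175, one-sided, 11550 assignments). With subarray loess the excess was 0.214 (exact permutation p = 0.00364, one-sided), which leaves a clone signal in the levels as a hypothesis. Infected pairs (1 with 2, 1 with 3, 2 with 3) then correlated at 0.368, 0.0211 and 0.130 in the low clone. In the medium clone they gave 0.0269, 0.349 and 0.0809, and in the high clone -0.173, -0.0824 and -0.0155. High pairs 1 with 2 and 2 with 3 exceeded array error only because it gave -0.424 and -0.450. That error left out variance between ramets.

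Whether the clone differences also exist without the fungus could not be settled. At the 29 probes that passed between infected medium and low clones with subarray loess, the wounded ramets differed in the same direction at 29 of 29, by a median of 0.635 (95% bootstrap interval 0.472 to 0.752) against 0.780 in infected ramets. After global loess 26 of these 29 had the same direction, with a median of 0.850 (95% bootstrap interval 0.537 to 1.06) against 0.881. The bootstrap resampled the 29 probes and not ramets. Its intervals hold no spread between wounded ramets, of which each clone had 1. Shared array error alone would carry a difference of 0.780 over to 1.02 in the wounded ramets, more than a fully shared clone difference would, so the 2 cannot be told apart with this loop.

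Whether the 2 clones share a response to infection beyond wounding could not be settled, since each response rests on 1 wounded ramet and 0 probes passed in either, with 74 and 22 under an unadjusted 0.05. Over 2688 probes their log2 differences correlated at -0.122 after global loess and at 0.0577 with subarray loess, where shared array error alone gives -0.0296. The sign was the same at 44.2% and 51.5% of probes. Such values do not show that the responses differ.

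Predicted from the levels of its ramets estimated without it, an array's log ratios correlated with the prediction at a median of 0.309 after global loess, with 4 of 21 arrays below 0. The 2 lowest, -0.154 and -0.185, were the arrays of the dye swap that correlated above 0. With subarray loess the median was 0.335 and 0 arrays lay below 0.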
